A study of Sus scrofa with 16 samples.

How the data were processed

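Upstream of the files, per the labels, macrophages from lung lavage were frozen, thawed and cultured for 24 h before infection or mock infection. RISC was precipitated with an antibody to all Argonaute proteins, and 10 ng of the bound RNA was labelled with Cy3 and hybridised to a custom porcine array. Per the file headers, the scans were read by Agilent Feature Extraction 10.7.3.1. The probe intensity in the scanner files as deposited had the background subtracted and trends within the array removed, and a signal not above background was replaced by a surrogate value, per the file headers. The mean, median and background intensities per spot were deposited as raw pixel brightness. The scanner's flags for signals well above background, for saturation and for outlying spots were used as deposited. Software for the steps between the scanner files and the series table is not given in the sources used here.

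The log2 values of the authors' series table are the binary logarithm of the median spot signal minus 1 constant per array, without background subtraction; this was found by comparing the table with the scanner files. Each of its 16 columns equalled, within 1e-06 over 59325 probes, the scanner file of the same animal and time in the opposite infection group. Viral probes follow the labels in the scanner files, so these files were used with the groups of the sample labels. The table by its own headers was kept as an alternative, in which the differences of genes had a Pearson r of -0.897 (7 h), -0.884 (10 h) and -0.916 (both times) across genes with those of the scanner files.

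The array held 60422 probes of 60 nt. A gene name was given to 29453 of them, 17984 by their symbol, 7353 by an accession, 813 by a listed accession, 191 by a synonym and 3112 by the name in the file; 30850 stayed unnamed and 119 were viral. The processed signal was taken to log2, 230 spot values marked as outlying were left out, repeated spots were averaged, and each array was set to the 75th percentile of the 18961 host probes well above background on all arrays. Probes well above background on at least 4 of 16 arrays were kept (30990), and the brightest probe stood for a gene, which gave 19512 genes and unnamed transcripts, 9314 of them named. Of the named genes 4520 had several probes, and 44 at 7 h and 51 at 10 h had probes called in opposite directions. Where a probe was above background on no array of a group, a lower bound of the fold change is given.

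Groups were those of the sample labels: control and infected at 7 h and 10 h, with 4 animals each. R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table fitted the 4 group means, with moderated two-sided t tests (3.12 prior degrees of freedom) and Benjamini-Hochberg adjustment within each comparison; a gene was called at an adjusted p under 0.05. Gene lists were tested with cameraPR at a preset correlation of 0.01, two-sided, adjusted over 28 lists and the 3 infection comparisons. The estimated correlation refers to camera, and fry is limma's rotation test of a list against no change, not against other genes. Viral probes were compared by the exact permutation test over the 70 assignments of 8 arrays, two-sided. The lists are named in the report.

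The comparisons, lists and first alternatives were fixed before the data were examined. These alternatives were the animal as block, the array median, quantile normalisation, normexp background correction with an offset of 50, the authors' table, no filter or all 16 arrays in the filter on dim probes, the slide as random block, the scan day as block with and without the animal, trend and robust variance, array weights, only the 8 arrays compared, every probe on its own, the mean of the probes of a gene, each array or animal left out, camera with an estimated correlation, and fry. Added afterwards were the 75th percentile over all probes, removal of the GC trend with and without the animal as block, omission of the 10 h control arrays of animals 123 and 124, the animal as block with an estimated correlation, and list tests of the difference between times and of time in control cells.

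Named genes were chosen from the 10 largest rises and falls of each comparison, the 4 members of each list with the smallest p at 7 h and at 10 h, and 2 entry receptors and the Argonaute genes, all fixed beforehand. Of these, some genes were left out of the text for length, mostly those whose call ended under many alternatives. In the 2 comparisons between times, where no gene passed, genes with the smallest p were named. The 4 arrays of an animal were paired by the labels. As a check, deviations from the group means had a correlation over 0.1 in 15 of 24 array pairs of the same animal (median 0.182) and a median of -0.052 in 72 pairs of different animals, across genes. In a self-test with known shifts in simulated groups, 100 genes were shifted by 1 or 2 on the log2 scale. In separate simulations for the comparisons between times only 1 group was shifted. The fit called 9% and 67% of them at 7 h, 13% and 72% at 10 h and 46% and 88% over both times, with 0 to 2 of 19241 unshifted genes called. It called 1% and 37% of them for the difference between times and 10% and 71% for control time, with 1 of 19312 unshifted genes called in each. A list of 71 members shifted by 0.7 was found in all 3 comparisons, with 0 of 27 other lists called by limma's test. The simulated genes varied independently of one another, so this does not show how often lists of correlated genes are called without a shift. Some results of single genes are not reported here. Total RNA was not used here, and unnamed probes are counted but not described.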

Results

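RNA bound to the RNA-induced silencing complex (RISC), the Argonaute-containing complex through which microRNAs act on mRNAs, was measured on 16 single-colour oligonucleotide arrays. The cells were porcine alveolar macrophages washed from the lungs of 4 pigs and cultured. They were infected at a multiplicity of infection of 2 with the Finistère strain of porcine reproductive and respiratory syndrome virus (PRRSV), an RNA virus that replicates in these macrophages, or were mock infected. Cells were harvested 7 h or 10 h later and RISC was precipitated with an antibody that binds all 4 Argonaute proteins of mammals. Each of the 4 groups (control and infected at 7 h and at 10 h) held 4 arrays, 1 from each of animals 123 to 126. The share of probes well above background was 49.7% ± 5.28 (SD, n = 4) in controls at 7 h and 45.8% ± 2.8 in infected cells at 7 h. It was 41.8% ± 5.96 in controls at 10 h and 45.4% ± 3.46 in infected cells at 10 h, with the lowest values, 37.7% and 35.8%, on the 10 h control arrays of animals 123 and 124. No probe was saturated, and precision is limited by the number of arrays. Total RNA of the same cells was not analysed here, so a difference can lie in the amount of a transcript in the cell or in the share of it held by RISC. The 16 arrays also held no precipitate made without the antibody. RNA bound to RISC and other RNA in the precipitate therefore cannot be told apart.

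Whether RISC-bound RNA of infected cells contained viral RNA was asked first, which also checks the labels. RNA of the infecting strain was abundant on every infected array and near background on every control array. The 19 Finistère probes without a suffix in their name had a mean array median of -9.27 ± 0.85 (normalised log2 signal, SD, n = 4) in controls and 4.32 ± 0.52 in infected cells at 7 h, and of -8.22 ± 0.77 and 5.90 ± 1.09 at 10 h. Of these probes 12 at 7 h and 14 at 10 h were above background on no control array, so their control values are floors rather than measurements. The probe for ORF6, which encodes the viral membrane protein, was at least 23300-fold higher in infected cells at 7 h and at least 26800-fold higher at 10 h. The probe for ORF7, which encodes the nucleocapsid, was higher by 16.72 on the log2 scale at 7 h and by 15.40 at 10 h, and was above background on 2 of 4 control arrays at each time. Viral probes made up 1.96% to 9.08% of the signal of the infected arrays and at most 0.00297% of that of the control arrays. Probes with the suffix minus, of which 16 at 7 h and 15 at 10 h were above background on no control array, were higher by at least 4.88 to 8.84 and at least 2.71 to 9.00 on the log2 scale. Those with the suffix Rev (15 and 16 such probes) were higher by at least 4.67 to 9.37 and at least 1.69 to 8.87. The sources used here do not say what these suffixes stand for. For each of these kinds of Finistère probe the exact permutation test gave p = 0.0286 (two-sided, n = 4 against 4), the smallest value that 4 arrays against 4 allow. Between 7 h and 10 h the probes without a suffix were higher by 1.58 in infected cells, in 4 of 4 animals, a difference that did not pass (exact permutation p = 0.0857, two-sided, n = 4). That test does not use the pairing of the arrays by animal. Within the 5 slides and 4 scan days that held both groups the signal of infected arrays lay 12.36 to 15.88 above that of control arrays, which was mostly not above background. Such comparisons within a slide or scan day hold few arrays, some only 1 against 1. Several set different animals or times against each other, and 1 slide and 1 scan day hold the same 2 arrays. On the 10 h control arrays of animals 123 and 124 the probes for ORF7 (-3.37 and -5.01) and polyA (-3.99 and -4.17) were above background, and on the other 10 h control arrays they were not (-8.99 to -8.11). The lowest signal of a host probe above background was -5.57 and -5.35 on these 2 arrays, against -6.89 and -7.02.

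**Figure D1:**
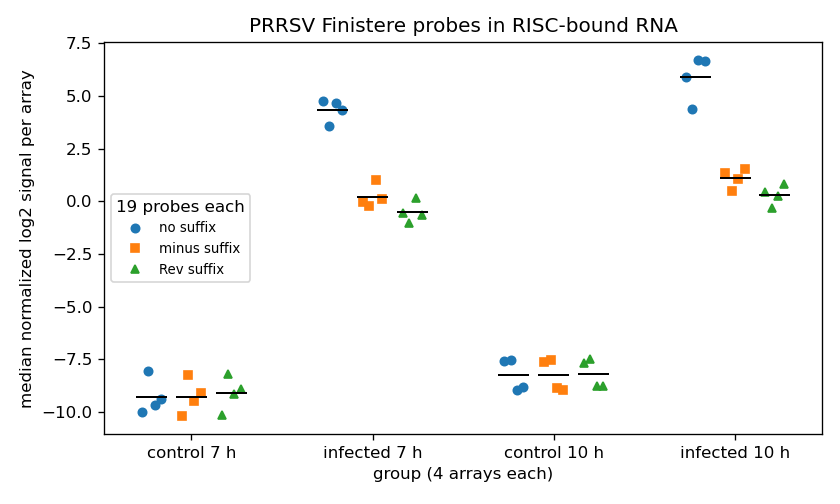
Median normalised log2 signal of the 19 Finistère probes of each kind (y axis) on each array, by group (x axis); each point is 1 array and each line the mean of 4. All infected arrays lie above all control arrays for each kind of probe, with means of 4.32 against -9.27 at 7 h and 5.90 against -8.22 at 10 h for probes without a suffix.

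Which host transcripts were higher or lower in the precipitate after 7 h of infection was asked next. Several interferon-stimulated genes were among the largest rises and several genes of the mitochondrial genome among the largest falls. ISG12(A), an interferon-induced gene, rose by 3.13 ± 0.51 (log2, SE, n = 4 against 4; adjusted p = 0.000693), which is 8.74-fold. RSAD2, which encodes the antiviral enzyme viperin, rose by 2.82 ± 0.47 (adjusted p = 0.000798), and ISG15, a ubiquitin-like protein conjugated to other proteins in the interferon response, by 2.68 ± 0.29 (adjusted p = 2.98e-05). OAS2, an RNA sensor that activates RNase L, rose by 2.71 ± 0.63 (adjusted p = 0.00848), and IL29, a type III interferon above background on 2 of 4 control arrays, by 2.68 ± 0.41 (adjusted p = 0.000463). The keratin KRT75, the GTPase gene RAB37 and the secreted protein gene FAM3D, none above background on any 7 h control array, were at least 3.44-fold, 3.76-fold and 3.52-fold higher. KRT75 was above background on 3 of 4 infected arrays. CYTB, the mitochondrial cytochrome b, fell by 4.10 ± 0.34 (adjusted p = 6.19e-06), which is 17.1-fold. The mitochondrial genes ND1, ND3 and ATP6 fell by 3.48 ± 0.47, 3.27 ± 0.43 and 3.26 ± 0.36. CCDC75 fell by 3.35 ± 0.26 (adjusted p = 4.81e-06), and CCDC59, above background on 1 of 4 infected arrays, fell by 3.99 ± 0.34. NOP58, a core protein of box C/D small nucleolar ribonucleoproteins, fell by 3.29 ± 0.47.

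Among the 19512 genes and unnamed transcripts tested at 7 h with limma (two-sided), 1844 rose and 1998 fell at an adjusted p under 0.05. Of these, 940 rising and 1202 falling ones carried a gene name. The median of all genes was 0.375 above 0 at 7 h and 0.203 at 10 h, so gene lists are given relative to that median. Differences of single genes and counts of rises and falls are given against 0, so small rises stand closer to the other genes than their values say. With the animal as block 2942 rose and 2442 fell (54.6% rises). Rises made up 48% of the calls here, 32.5% under quantile normalisation, and from 22.2% (without animal 125) to 71.1% (animal and scan day as blocks) over all alternatives but the authors' table, which reversed directions. Leaving out 1 animal gave 1400 calls (animal 123), 1668 (125) or 1836 (126), and leaving out the 7 h control array of animal 123 gave 2341. Correction of the background by normexp gave 1708 calls and ended those of KRT75, RAB37, FAM3D and IL29. Averaging the probes of a gene ended that of RSAD2, and leaving out animal 123 or 124 that of OAS2. Across genes, which are not independent replicates, the difference rose with the GC content of the probe (Spearman rho = 0.348), and within slides and scan days that held both groups rho was 0.307 to 0.433 over both times. The arrays compared within a slide or scan day partly came from different animals and times.

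The same question at 10 h again had interferon-stimulated genes among its largest rises. RSAD2, on a probe not above background on any 10 h control array, was at least 13.4-fold higher; another of its probes was above background on 3 of 4 controls. ISG15 rose by 3.06 ± 0.29 (log2, SE, n = 4 against 4; adjusted p = 5.97e-06), or 8.31-fold. IFITM1, which restricts the entry of enveloped viruses, rose by 2.98 ± 0.50 (adjusted p = 0.000655) and OAS2 by 2.76 ± 0.63 (adjusted p = 0.00579). RTP4, an interferon-induced gene above background on 1 of 4 controls, rose by 3.37 ± 0.62 (adjusted p = 0.00122). CCDC59, not above background on any infected array, was at least 10.5-fold lower, and CCDC75 fell by 3.78 ± 0.26 (adjusted p = 1.58e-06). ACADM, an enzyme of mitochondrial fatty acid oxidation, fell by 3.74 ± 0.31 (adjusted p = 2.91e-06). MRPL47, a mitochondrial ribosomal protein above background on 2 of 4 infected arrays, fell by 3.55 ± 0.21 (adjusted p = 4.53e-07). NOP58 and CYTB fell by 3.53 ± 0.47 and 3.43 ± 0.34. FRG1 and IFT80, each above background on 3 of 4 infected arrays, fell by 3.39 ± 0.38 and 3.37 ± 0.41.

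At 10 h, 2204 genes and unnamed transcripts rose and 2434 fell, among them 1261 and 1452 with a gene name (limma, two-sided, adjusted p under 0.05). With the animal as block 3246 rose and 2859 fell (53.2% rises). Rises made up 47.5% of the calls here, and from 27% (no filter on dim probes) to 55.5% (array median) over the same alternatives. Normexp correction gave 2078 calls, 29.6% of them rises, and ended that of RTP4. Leaving out animal 123 gave 2357 calls and animal 124 gave 2856; without animal 123 the call of OAS2 ended. Without the 10 h control arrays of animals 123 and 124, which had the lowest share of probes above background, 2440 genes were called. The rise of the difference with probe GC content had a rho of 0.396 across genes.

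Both times together, which weigh the 7 h and 10 h differences equally and ask for the common response with more precision, gave 4789 rises and 3175 falls (2506 and 1864 with a gene name). The 8 arrays of each group came from 4 animals and were fitted without a term for the animal; with the animal as block there were 5917 rises and 3508 falls. ISG15 rose by 2.87 ± 0.20 (log2, SE, n = 8 arrays of 4 animals against 8; adjusted p = 1.33e-07, or 8.3e-07 with the animal as block), ISG12(A) by 2.92 ± 0.36, IFITM1 by 2.75 ± 0.35 and OAS2 by 2.74 ± 0.45, each in 8 of 8 within-animal differences. CCDC75 fell by 3.56 ± 0.18 (adjusted p = 2.01e-08), BCAS2, a component of the spliceosome, fell by 3.25 ± 0.17, and MRPL47 fell by 3.25 ± 0.15 (adjusted p = 1.07e-08). CYTB fell by 3.76 ± 0.24 and ACADM by 3.46 ± 0.22. Normexp correction gave 3927 calls over both times. Rises made up 60.1% of the calls here, and from 49.6% to 66.6% (array median) over all alternatives but the authors' table. The lowest share was without animal 125, with 2760 rises and 2802 falls. Of the genes called at each time, 929 rose at both (208.3 for independent lists of that size) and 1740 fell at both (249.2), and 0 were called in opposite directions in limma's test at 7 h and 10 h. The differences at 7 h and 10 h had a Pearson r of 0.767 across genes.

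**Figure D2:**
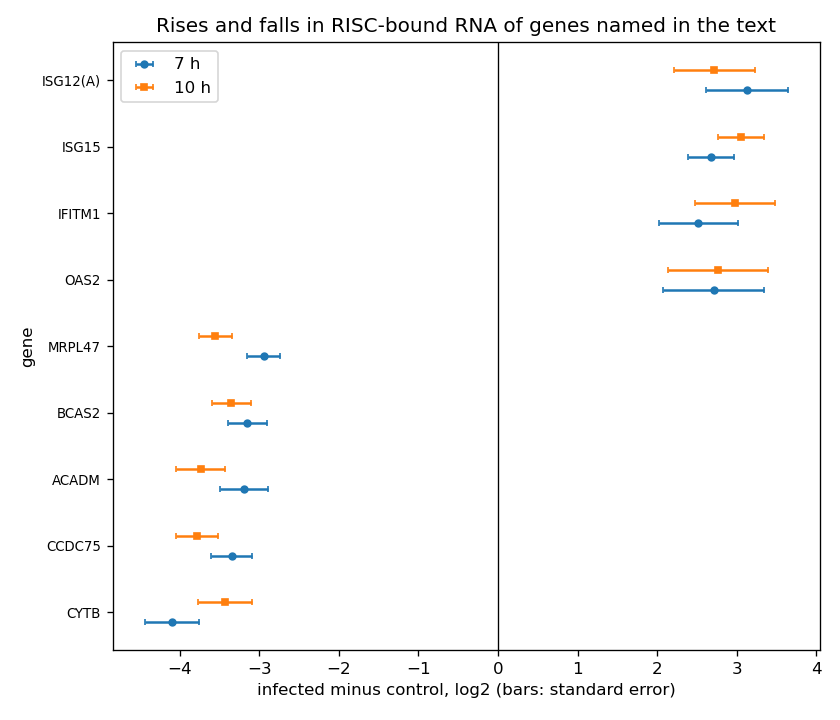
Infected minus control difference (x axis, log2) at 7 h and 10 h of the genes named above for both times together (y axis); points are fitted values from 4 against 4 arrays and bars standard errors. ISG12(A) has the largest rise over both times among them and CYTB the largest fall.

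The interferon system was examined through a list of interferon-stimulated genes and a list of interferon genes. Of 42 interferon-stimulated genes tested, 15 rose and 1 fell at 7 h, and 29 rose and 2 fell at 10 h. Adjusted over the list alone, 21 rose and 2 fell at 7 h and 31 rose and 3 fell at 10 h. Relative to all genes their median was 0.47 higher at 7 h (adjusted p = 0.000528), 1.37 higher at 10 h (adjusted p = 1.96e-13) and 1.10 higher over both times (adjusted p = 6.57e-09), in 4 of 4 animals at each time. With an estimated correlation the adjusted p was 0.983 in each of these comparisons. Fry, which tests a list against no change rather than against all genes, gave 0.0131 at 7 h and 0.00101 at 10 h. PARP12, a mono-ADP-ribosyltransferase, rose by 1.66 ± 0.25 at 7 h (adjusted p = 0.000316). ISG20, an antiviral exonuclease, rose by 2.58 ± 0.40 (adjusted p = 0.000484). USP18, which removes ISG15 from proteins, rose by 2.30 ± 0.23 at 10 h (adjusted p = 1.04e-05). ZBP1, a sensor of nucleic acids above background on 2 of 4 controls, rose by 2.55 ± 0.24 (adjusted p = 5.97e-06). Normexp correction ended the ZBP1 call. Of the 4 members of the interferon gene list that were tested, 1 rose at 7 h and 2 at 10 h, likewise when adjusted over the list alone. IL29 is an older name of IFNL1, which is on this list, but it was not matched to it. The counts and adjusted p of the interferon gene list therefore leave out the rise of IL29 at 7 h. IFN-ALPHA-10 rose by 0.97 ± 0.24 at 7 h (adjusted p = 0.0127), a call that ended without the filter on dim probes, with the GC trend removed and without animal 123, 125 or 126. The interferon genes lay 0.80 above all genes at 7 h (adjusted p = 0.644) and 0.06 above at 10 h (adjusted p = 0.832), where their median fell from 0.265 to 0.155 with genes set to their bound. The median of the interferon-stimulated genes stayed at 1.57. Within slides and scan days the difference of the interferon-stimulated list was 0.35 to 1.39 above that of all genes. Both ends of this range come from 1 infected against 1 control array of different animals.

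Protein synthesis and mitochondrial energy production were examined through 3 lists. Of 36 translation factors, 2 rose and 8 fell at 7 h and 4 rose and 11 fell at 10 h (2 and 9, and 6 and 12, adjusted over the list alone). Their median lay 0.73 below that of all genes at 7 h (adjusted p = 0.00295; 4 of 4 animals), 0.39 below at 10 h (adjusted p = 0.101) and 0.55 below over both times (adjusted p = 0.0148). With an estimated correlation the adjusted p of translation factors was 0.983 in each comparison. EIF3E and EIF3J, subunits of an initiation factor, fell by 2.15 ± 0.23 and 2.22 ± 0.27 at 7 h and by 2.48 ± 0.23 and 2.30 ± 0.27 at 10 h. EIF2S1, which carries the phosphorylation site of the integrated stress response, fell by 1.84 ± 0.21 at 7 h (adjusted p = 5e-05) and 1.65 ± 0.21 at 10 h. EIF4E, the cap-binding protein, fell by 1.96 ± 0.26 at 10 h (adjusted p = 8.03e-05). Of 73 ribosomal protein genes, 7 rose and 12 fell at 7 h and 2 rose and 15 fell at 10 h (7 and 13, and 2 and 15, adjusted over the list alone). RPL5 fell by 1.83 ± 0.20 and 2.01 ± 0.20 (adjusted p = 9.51e-06 at 10 h). The list lay 0.21 below all genes at 7 h (adjusted p = 0.782) and 0.46 below at 10 h (adjusted p = 0.0487), or 0.983 at both times with an estimated correlation. Of 50 nuclear genes of oxidative phosphorylation, 1 rose and 5 fell at 7 h and 3 rose and 15 fell at 10 h (1 and 3, and 3 and 18, adjusted over the list alone). UQCRB, a subunit of complex III, fell by 2.03 ± 0.20 and 2.76 ± 0.20 (adjusted p = 2.44e-06 at 10 h). NDUFB3, a subunit of complex I, fell by 1.21 ± 0.20 and 1.55 ± 0.20 (adjusted p = 8.71e-05 at 10 h). The list lay 0.41 below all genes at 7 h (adjusted p = 0.289), 0.56 below at 10 h (adjusted p = 0.0102; 4 of 4 animals) and 0.52 below over both times (adjusted p = 0.0487). With an estimated correlation its adjusted p was 0.983 in each comparison.

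Against no change, which is what fry tests, the adjusted p was 0.0131 for translation factors at 7 h. With the animal as block the adjusted p was 0.0691 for the ribosomal list at 10 h, 0.0973 for oxidative phosphorylation over both times and 0.055 for translation factors over both times. Over all alternatives without an estimated correlation these 3 adjusted p ranged from 3.74e-05 to 0.905, from 7.11e-05 to 0.44 and from 1.72e-07 to 0.0869. These 3 calls were lost in 28 of 41, 24 of 40 and 6 of 40 alternatives. The oxidative phosphorylation call at 10 h was lost in 11 of 41: with scan day as block, alone or with the animal, with the slide as random block, with only the 8 arrays compared, and with the GC trend removed and the animal as block. It was also lost without animal 124, animal 125 or the 10 h control array of animal 125, in fry, and with an estimated correlation, alone or with the animal as block. The interferon-stimulated calls and that of translation factors at 7 h were lost in 2 alternatives each, those with an estimated correlation. Within slides and scan days the lists lay below all genes, by 0.04 to 0.67 for translation factors, by 0.001 to 0.66 for ribosomal proteins and by 0.004 to 0.68 for oxidative phosphorylation. These comparisons rest on few arrays, partly of different animals and times. The 13 protein-coding genes of the mitochondrial genome, a set chosen after its values were seen, were tested as well: 11 fell at 7 h and 11 at 10 h, with a median 2.62 and 2.47 below that of all genes. COX1, at -1.40 ± 0.66 (adjusted p = 0.133) and -1.21 ± 0.66 (adjusted p = 0.2), passed at neither time. ND6 did not pass at 7 h and COX3 did not at 10 h.

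Genes that encode the immunoprecipitated complex and known microRNA targets were examined because RISC-bound RNA was measured. The values below are of mRNA in the precipitate, not of Argonaute or other proteins. AGO1 rose by 1.37 ± 0.32 at 7 h (log2, SE, n = 4 against 4; adjusted p = 0.00799), a call that ended under normexp correction and without animal 123, and stood at 0.81 ± 0.32 at 10 h (adjusted p = 0.0746). AGO2, the only Argonaute of mammals that cleaves target RNA in most tissues, stood 0.81 ± 0.25 higher at 7 h (adjusted p = 0.031) and 0.39 ± 0.25 at 10 h (adjusted p = 0.278). The AGO2 call at 7 h ended in 16 of 37 alternatives, where its difference was 0.43 to 0.93. These were quantile normalisation, normexp correction, no filter on dim probes, trend and robust variance, only the 8 arrays compared, the probes of a gene averaged, and the GC trend removed, with and without the animal as block. The others left out animal 123, 125 or 126, the 7 h control array of 123, 125 or 126, or the 7 h infected one of 124 or 125. AGO4 differed by 0.49 ± 0.36 and 0.19 ± 0.36 (adjusted p = 0.324 and 0.753), and AGO3 had no probe that passed the filter. These differences are against 0, while the median of all genes was itself 0.375 at 7 h and 0.203 at 10 h. Of 29 genes of the microRNA machinery, 5 rose and 3 fell at 7 h and 6 rose and 5 fell at 10 h (9 and 3, and 6 and 5, adjusted over the list alone). DDX17, an RNA helicase of the microprocessor, rose by 1.98 ± 0.23 at 7 h (adjusted p = 4.57e-05), while its paralogue DDX5 fell by 1.72 ± 0.29 at 10 h (adjusted p = 0.000614). FXR1, an RNA-binding protein of the fragile X family, fell by 1.38 ± 0.24 and 1.52 ± 0.24 (adjusted p = 0.000399 at 10 h). Of 52 established microRNA targets, 13 rose and 2 fell at 7 h and 10 rose and 4 fell at 10 h (16 and 3, and 14 and 6, adjusted over the list alone). The transcription factor gene FOXO3 rose by 1.44 ± 0.25 at 7 h (adjusted p = 0.0013). SMAD4, the shared mediator of TGF-beta signalling, fell by 1.59 ± 0.23 at 10 h (adjusted p = 0.000199). Neither list passed: the machinery lay 0.06 above and 0.02 below all genes (adjusted p = 0.782 and 0.922) and the targets 0.24 and 0.11 above (adjusted p = 0.256 and 0.757).

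Genes of pathogen sensing and inflammation moved in both directions, as did the genes tested as a whole. Of all 19512, 1844 rose and 1998 fell at 7 h, and 2204 rose and 2434 fell at 10 h. Of 29 genes of pattern recognition and its signalling, 3 rose and 5 fell at 7 h and 3 rose and 4 fell at 10 h (3 and 5, and 4 and 4, adjusted over the list alone). TBK1, the kinase that activates IRF3, was 2.84-fold lower at 10 h (adjusted p = 0.0011), IRAK4, a kinase downstream of Toll-like receptors, fell by 1.19 ± 0.22 (adjusted p = 0.00142) and LY96, the co-receptor of TLR4, fell by 1.69 ± 0.26 (adjusted p = 0.00029). MAVS, the mitochondrial adaptor of RIG-I signalling, rose by 1.18 ± 0.21 at 10 h (adjusted p = 0.00108), a call that ended with animal and scan day as blocks. Of 25 proinflammatory cytokine and chemokine genes, 0 rose and 1 fell at 7 h and 3 rose and 3 fell at 10 h in limma's test. Adjusted over the list alone, 0 changed at 7 h and 3 rose and 3 fell at 10 h. IL18, a cytokine released by inflammasomes, fell by 1.40 ± 0.35 at 10 h (adjusted p = 0.00966), a call that ended with the GC trend removed and without animal 124 or 125. TNF stood at 1.01 ± 0.39 at 7 h (adjusted p = 0.079). With the animal as block TNF passed (adjusted p = 0.0194; 0.00211 to 0.352 over all alternatives). Of 22 genes of NF-kB feedback and anti-inflammatory control, 1 rose and 1 fell at 7 h and 4 rose and 2 fell at 10 h (0 and 1, and 5 and 3, adjusted over the list alone). NFKBIZ, an atypical inhibitor of NF-kB above background on 1 of 4 infected arrays, fell by 2.86 ± 0.64 at 10 h (adjusted p = 0.00482) except under normexp correction. PPARG, a nuclear receptor of alveolar macrophages, fell by 1.29 ± 0.29 at 10 h (adjusted p = 0.00548), a call that ended with animal and scan day as blocks and without animal 126. Relative to all genes the 3 lists lay between -0.18 and 0.04 (adjusted p = 0.832 to 0.999).

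Macrophage identity and virus entry were examined because PRRSV enters macrophages through SIGLEC1 and CD163. SIGLEC1, a sialic acid receptor, rose by 1.71 ± 0.41 at 10 h (log2, SE, n = 4 against 4; adjusted p = 0.00742), a call that ended with scan day as block, alone or with the animal, and without the 10 h control arrays of animals 123 and 124. Its 7 h difference was 1.32 ± 0.41 (adjusted p = 0.0355), a call that ended in 11 of 38 alternatives, at 1.01 to 1.56. These were no filter on dim probes, only the 8 arrays compared, the GC trend removed, and omission of animal 123, 125 or 126, of the 7 h control array of 124 or 126, or of the 7 h infected one of 123, 125 or 126. CD163, the scavenger receptor that PRRSV needs, stood at -0.80 ± 0.36 at 7 h (adjusted p = 0.125) and -0.72 ± 0.36 at 10 h (adjusted p = 0.166), in 4 of 4 animals. With the animal as block it passed (adjusted p = 0.0173 and 0.023), with adjusted p of 0.0147 to 0.331 and 0.0215 to 0.443 over all alternatives. Of 10 entry factors, 2 rose and 0 fell at 7 h and 2 rose and 2 fell at 10 h in limma's test (2 and 0, and 3 and 2, adjusted over the list alone). Of 33 alveolar macrophage markers, 3 rose and 4 fell at 7 h and 4 rose and 4 fell at 10 h, with the same counts when adjusted over the list alone. CD36, a receptor for oxidised lipids, fell by 1.87 ± 0.24 and 1.89 ± 0.24 (adjusted p = 7.15e-05 at 10 h). Of 13 markers of M2 polarisation, 3 rose and 2 fell at 7 h and 5 rose and 1 fell at 10 h (4 and 2, and 5 and 2, adjusted over the list alone). CCL17, a chemokine for CCR4-bearing T cells, rose by 2.34 ± 0.40 and 2.61 ± 0.40 (adjusted p = 0.000274 at 10 h).

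Of 30 genes of antigen presentation, 8 rose and 2 fell at 7 h and 5 rose and 3 fell at 10 h, with the same counts when adjusted over the list alone. PSMB9, a subunit of the immunoproteasome, rose by 1.11 ± 0.17 and 0.88 ± 0.17 (adjusted p = 0.0018 at 10 h). TAP1, the peptide transporter, rose by 1.44 ± 0.25 at 10 h (adjusted p = 0.000877) except with animal and scan day as blocks. PDIA3, a chaperone of peptide loading, fell by 1.95 ± 0.30 and 1.64 ± 0.30 (adjusted p = 0.00121 at 10 h). CTSS, a lysosomal protease, was 2.29-fold lower at 7 h (adjusted p = 0.00412). Relative to all genes the entry factors lay at -0.24 and 0.01, macrophage markers at -0.28 and -0.04, M2 markers at -0.04 and 0.46, and antigen presentation at -0.01 and 0.24. The adjusted p of these 4 lists were 0.922 and 0.867, 0.782 and 0.979, 0.879 and 0.782, and 0.619 and 0.151.

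Chaperones, the stress response and cell death included genes that rose and genes that fell, without a call for any of their lists. Of 27 genes of the unfolded protein response, 4 rose and 4 fell at 7 h and 3 rose and 4 fell at 10 h (5 and 4, and 3 and 4, adjusted over the list alone). HSP90B1, a chaperone of the endoplasmic reticulum, fell by 2.16 ± 0.33 and 2.05 ± 0.33 (adjusted p = 0.00048 at 10 h). DNAJB11, a co-chaperone gene of the same compartment, fell by 1.29 ± 0.22 and 1.30 ± 0.22 (adjusted p = 0.000644 at 10 h). Of 21 heat shock and immediate early genes, 1 rose and 3 fell at 7 h and 0 rose and 3 fell at 10 h in limma's test, with the same counts when adjusted over the list alone. HSPD1, a mitochondrial chaperonin, fell by 2.30 ± 0.29 and 2.03 ± 0.29 (adjusted p = 0.000202 at 10 h). Of 23 apoptosis genes, 3 rose and 4 fell at 7 h and 5 rose and 4 fell at 10 h (3 and 4, and 6 and 5, adjusted over the list alone). CASP8, the initiator caspase of death receptors, fell by 1.23 ± 0.24 at 10 h (adjusted p = 0.00194). Of 26 genes of autophagy and lysosomes, 4 rose and 5 fell at 7 h and 8 rose and 5 fell at 10 h (8 and 6, and 8 and 5, adjusted over the list alone). ATG3 and ATG5, which act in the lipidation of LC3, fell by 1.97 ± 0.29 and 1.41 ± 0.22 at 7 h (adjusted p = 0.000316 and 0.000536), as did OPTN, an autophagy receptor, by 1.24 ± 0.21 (adjusted p = 0.00112). The lysosomal enzyme HEXA and the autophagy kinase ULK1 rose by 1.27 ± 0.24 and 1.11 ± 0.23 at 10 h, calls that ended with animal and scan day as blocks. Relative to all genes these 4 lists lay at -0.04, -0.32, -0.25 and -0.01 at 7 h and at -0.17, -0.15, -0.47 and 0.07 at 10 h (adjusted p = 0.778 to 0.922).

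Of 24 genes of glycolysis and hypoxia, 4 rose and 4 fell at 7 h and 3 rose and 2 fell at 10 h, with the same counts when adjusted over the list alone. HIF1A, the oxygen-regulated transcription factor, fell by 1.80 ± 0.24 and 2.16 ± 0.24 (adjusted p = 2.12e-05 at 10 h). SLC2A1, the glucose transporter GLUT1, rose by 1.08 ± 0.23 at 10 h (adjusted p = 0.00337) except with animal and scan day as blocks. Of 21 genes of cholesterol synthesis and efflux, 4 rose and 1 fell at 7 h and 3 rose and 1 fell at 10 h (6 and 1, and 0 and 0 in limma's test, adjusted over the list alone). NR1H3, which encodes the liver X receptor alpha, rose by 0.83 ± 0.20 at 7 h (adjusted p = 0.0111), a call that ended under quantile normalisation, without the filter on dim probes, with the GC trend removed and without animal 123, 125 or 126. Of 11 histone genes, 0 changed at 7 h and 1 rose at 10 h in limma's test (0 and 0 adjusted over the list alone). Of 16 cell cycle genes, 1 rose and 2 fell at 7 h and 2 rose and 2 fell at 10 h (3 and 2, and 2 and 2, adjusted over the list alone). E2F1, a regulator of S phase entry, was 2.3-fold higher at 10 h (adjusted p = 0.0152), a call that ended without the filter on dim probes and without animal 125 or 126. The glycolysis, cholesterol, histone and cell cycle lists lay at -0.26, 0.06, -0.44 and -0.61 at 7 h and at -0.03, 0.16, -0.06 and -0.38 at 10 h relative to all genes (adjusted p = 0.619 to 0.922).

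Markers of other cells that a lung lavage can hold were followed beside the macrophage genes. Of 12 T and NK cell markers, 0 changed at 7 h and 1 rose at 10 h in limma's test. Of 13 neutrophil markers, 1 fell at each time. Of 10 B and plasma cell markers, 1 rose and 1 fell at 7 h and 3 rose and 1 fell at 10 h. BLNK, an adaptor of the B cell receptor, fell by 1.87 ± 0.27 and 2.45 ± 0.27 (adjusted p = 1.99e-05 at 10 h). Of 9 epithelial markers, 2 rose at 7 h and 1 at 10 h, of 8 fibroblast and endothelial markers 1 at each time, and of 9 erythroid and platelet markers 2 at 7 h and 3 at 10 h. GP9, a platelet glycoprotein, rose by 0.91 ± 0.18 at 7 h (adjusted p = 0.00347), a call that ended with the probes of a gene averaged, with the GC trend removed and without animal 123. Adjusted over the list alone, the rises and falls at 7 h and 10 h were 0 and 0, and 1 and 0, for T and NK cells, 3 and 1 at both times for B cells, and 0 and 1, and 0 and 0, for neutrophils in limma's test. They were 2 and 0, and 1 and 0, for epithelium, 1 and 0, and 2 and 0, for fibroblasts and endothelium, and 2 and 0, and 3 and 0, for erythroid cells and platelets. Relative to all genes the 6 lists lay at 0.29, 0.34, -0.22, 0.36, 0.19 and 0.36 at 7 h and at 0.26, 0.23, 0.19, 0.04, 0.19 and 0.05 at 10 h, in the order T and NK, B, neutrophil, epithelial, fibroblast and endothelial, and platelet (adjusted p = 0.61 to 0.922). With an estimated correlation no list passed at any time (lowest adjusted p = 0.983). Fry tests a list against no change, from which the median of all genes also differs, and so not against other genes. With it, antigen presentation (adjusted p = 0.0131), microRNA targets (0.00635), T and NK cells (0.0131), fibroblasts and endothelium (0.0131) and platelets (0.0267) passed at 7 h as well. At 10 h antigen presentation (adjusted p = 0.00786), translation factors (0.0239) and M2 markers (0.0424) passed in that test as well. For the NF-kB, entry factor, antigen presentation and M2 lists at 7 h and the machinery, glycolysis and histone lists at 10 h the relative median was below 0 while the direction of the test was up.

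**Figure D3:**
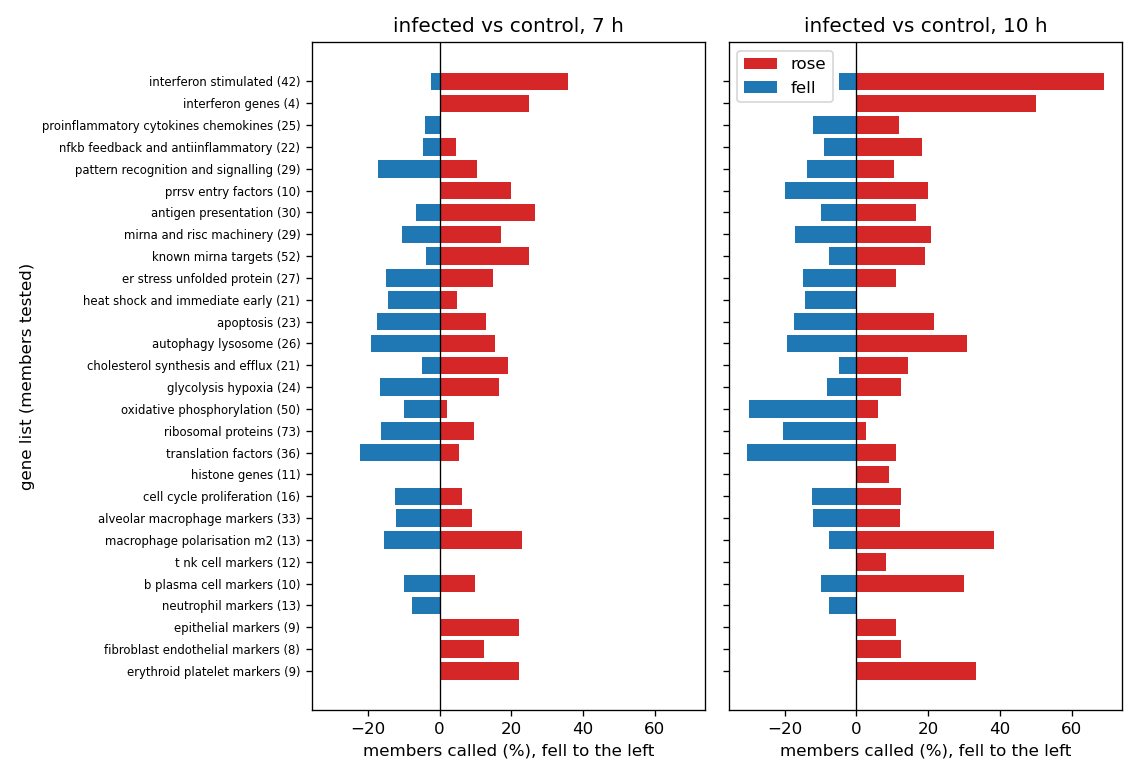
Share of the tested members of each gene list that rose (right of 0) or fell (left of 0) after infection (x axis, percent) at 7 h and at 10 h; the y axis names the list and its number of members. Interferon-stimulated genes have the largest share of rises, 15 of 42 at 7 h and 29 of 42 at 10 h, and translation factors fell in 8 and 11 of 36.

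Whether the response to infection differed between 10 h and 7 h was asked with the interaction of infection and time. No single gene passed: 0 genes at an adjusted p under 0.05 in limma's test, against 668 at an unadjusted p under 0.05, and 0 with the animal as block, against 1181. Nearest were DEPDC5, a repressor of mTORC1, at -1.57 ± 0.41 (log2, SE, n = 4 in each of 4 groups), ZBP1 at 1.27 ± 0.34 and CMPK2, an interferon-induced mitochondrial kinase, at 1.82 ± 0.49 (adjusted p = 0.972 for each). The interferon-stimulated list was tested for the difference between times after its values had been seen, and its median difference was 0.67 above that of all genes (adjusted p = 2.15e-12). Oxidative phosphorylation lay 0.16 below (adjusted p = 0.0182) and ribosomal proteins 0.10 below (adjusted p = 0.0038). With an estimated correlation the adjusted p was 0.904 for each of the 3 lists, and fry gave 0.848. The 10 h controls of this contrast include the arrays of animals 123 and 124, with the lowest share of probes above background. Between 7 h and 10 h the control arrays moved the opposite way for each of the 3 lists (values below). The difference between times can therefore lie in the controls and cannot be placed in the infected cells.

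Time in culture without virus, the background of the comparison between times, was asked of the control arrays. No gene passed between 10 h and 7 h: 0 genes in limma's test against 1227 at an unadjusted p under 0.05, and 0 with the animal as block against 1934. Nearest were SMARCA2, an ATPase of chromatin remodelling, at 1.16 ± 0.23 (log2, SE, n = 4 against 4; adjusted p = 0.72), NASP, a histone chaperone, at -1.14 ± 0.24, SLC39A10, a zinc transporter, at 1.44 ± 0.30 and TXNRD1, the thioredoxin reductase, at -0.94 ± 0.20, each in 4 of 4 animals. The number called was 1 without the filter on dim probes, 1 with scan day as block and 1 without the 10 h control arrays of animals 123 and 124. Among the lists, tested here after their values had been seen, interferon-stimulated genes lay 0.45 below all genes at 10 h (adjusted p = 1.62e-08), ribosomal proteins 0.28 above (adjusted p = 9.46e-11), oxidative phosphorylation 0.21 above (adjusted p = 1.67e-06) and cell cycle genes 0.26 below (adjusted p = 0.0106). With an estimated correlation the adjusted p was 0.904 for the first 3 and 0.528 for the cell cycle list. Of 35 splits of the 8 control arrays, 3 put the interferon-stimulated list as far from all genes.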

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

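Of the tests weighed here, the 3 tests of the GC trend, the set of mitochondrial genes and with it its 3 tests, the test for a mislabelled sample, the look at single viral probes and the list tests of the difference between times and of control time were chosen only after the result was seen. Chance flags about 1 in 20 groups as having a sample far from the others, and of 172 groups of 4 values tested 6 were picked out, against 8.6 expected by chance. The values were within-animal differences of lists and genes and, in each group of arrays, 4 measures of the arrays. All 6 picked out were within-animal differences. For the list of alveolar macrophage markers at 10 h the gap was 0.866 of the range, with animal 124 at -0.211 and the nearest at 0.13. PSMB9 at 10 h had a gap of 0.844 (animal 124 at 0.675, nearest 0.931), and ATG5 at 7 h of 0.866 (animal 124 at -0.872, nearest -1.54). ULK1 at 10 h had a gap of 0.886 (animal 124 at 1.302, nearest 1.059). For animal 125 at 10 h, the gap was 0.912 for HIF1A (-1.518, nearest -2.324) and 0.949 for EIF3J (-1.147, nearest -2.655).

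A difference between times was picked out for 3 lists: interferon-stimulated genes 0.67 above all genes in the 10 h minus 7 h difference, oxidative phosphorylation at -0.164 and ribosomal proteins at -0.101, none of which passed with an estimated correlation (adjusted p = 0.904). For each of these lists the control arrays alone moved the opposite way between 7 h and 10 h. A signal outside the report's comparisons was seen on the probes for the Lena strain, another strain of the virus, whose probes without a suffix had a median signal 10.513 (7 h) and 10.71 (10 h) higher on infected arrays (exact permutation p = 0.0286, two-sided, n = 4 against 4). These are no measured fold changes, since 18 of 20 of these probes at 7 h and 16 at 10 h were above background on no control array and 14 of 20 on all infected arrays. The single probes ran from 0.612 to 15.745 at 7 h and from -0.557 to 16.215 at 10 h. The infecting strain was Finistère, and which RNA the Lena probes bound was not tested, so the signal does not show Lena RNA.

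Transcripts encoded in the mitochondrial genome were lower in infected arrays, at -2.53 relative to all genes over both times. GC content was tested by removing its trend with the animal as block, which left -2.33, and scan day by adding it with the animal as blocks, which left -2.14. Under quantile normalisation and normexp correction the value nearest 0 was -2.47 (other scalings by a constant per array cannot move it), so none of these 3 technical explanations accounts for the difference. RNA quality or labelling that differs with infection was not tested for these transcripts and cannot be told apart from a biological difference. As a hypothesis, infection may lower these transcripts or their share in the precipitate, which the -2.14 left after blocking leaves open; the RNA of whole cells was not used here.

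The infected minus control difference rose with the GC content of the probe. Within the scan days that held both groups the lowest Spearman rho was 0.31 across genes, and among the brightest 25% of genes it was 0.3, so neither scan day nor the background of dim probes accounts for the trend. The value of 0.31 comes from 1 infected and 1 control array of different animals. Every infected array lay above every control array in rho of its deviations, with a gap of 0.21 between the lowest infected and the highest control array. RNA quality or labelling that differs with infection cannot be told apart from a biological difference by this gap of 0.21. As a hypothesis, RISC of infected cells may hold more GC-rich transcripts, with the same gap of 0.21.

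The 2 probes for the infecting strain that were brightest on infected arrays, ORF7 and polyA, were above background on the 10 h control arrays of animals 123 (-3.37 and -3.99) and 124 (-5.01 and -4.17) and not on the other 10 h control arrays (-8.99 to -8.11), while at 7 h polyA was above background on all 4 control arrays (-7.80 to -5.38). The lowest signal of a host probe above background was -5.57 and -5.35 on the 2 arrays, so background alone does not account for these 2 probes, and the lowest infected array lay 11.1 above the higher of the 2 arrays, so a mislabelled sample does not either. Carry-over of a little infected RNA cannot be told apart from other sources of this signal: ORF6, the third brightest probe, was above background on neither array (-7.54 and -7.57), and the lower Spearman rho with the mean infected signal, 0.27, was taken over 19 probes of which 17 were not above background on each array. The 2 arrays were also the only ones of their scan day and had the lowest 75th percentiles of signal (8.88 and 8.64 on the log2 scale, against 10.535 and 10.686 on the other 10 h control arrays), so an effect of that day stays open. No biological explanation was tested, since the labels give no difference in treatment between these arrays and the other 10 h control arrays.

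Regrouping the arrays asked whether chance can be excluded. At 7 h 1 of 35 splits of the 8 arrays called as many genes as the real 3842 (highest other 0), and at 10 h 1 of 35 as many as the real 4638 (highest other 1). Only 8 of the 35 splits at each time part the 2 arrays of every animal, as the real one does. These are too few for a share under 0.05, with the real 3842 and 4638 against a highest other of 0 at both times. The remaining splits put both arrays of at least 1 animal in the same group. Over both times, 1 of 100 exchanges within animals called as many as the real 7964 (highest other 3410). These exchanges treat the 7 h and 10 h pairs of an animal as separate units, although all come from 4 animals. Exchanges of whole animals are too few for a share under 0.05, so chance is not excluded there either. For the difference between times and for control time the real number is 0, which any split reaches (35 of 35 for each, highest other 2 and 1), so the splits say nothing about them.

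For list calls, chance cannot be excluded: 28 of 35 splits at 7 h called as many as the real 2 (highest other 10), 23 of 35 at 10 h as many as the real 3 (highest other 11), with 5 of 8 at each time among splits that part every animal (highest other 6 and 4), and 50 of 100 exchanges over both times as many as the real 3 (highest other 5). The interferon-stimulated list was as far from all genes in 6 of 35 splits at 7 h (real 0.472, highest other 0.737), in 1 of 35 at 10 h (real 1.367, highest other 1.275) and in 1 of 100 exchanges over both times (real 1.096, highest other 0.927). Its unadjusted p (cameraPR, two-sided) was as small in 7 of 35 splits at 7 h (real 1.88e-05, lowest other 5.87e-14), in 4 of 35 at 10 h (real 2.33e-15, lowest other 3.02e-22) and in 11 of 100 exchanges over both times (real 1.57e-10, lowest other 2.33e-18). Chance cannot be excluded for this list by these p. For control time 3 of 35 splits put the list as far from all genes (real 0.448, highest other 0.519) and 2 of 35 gave a p as small (real 8.68e-10, lowest other 5.01e-15), so chance cannot be excluded there. For the difference between times it was 1 of 35 by size (real 0.67, highest other 0.606) and 1 of 35 by p (real 3.84e-14, lowest other 1.9e-12), but the 8 splits that part every animal are too few for a share under 0.05 (highest other 0.555).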

How the results depend on the processing

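The alternatives chosen only after the result was seen were the 75th percentile over all probes, the GC trend removed with and without the animal as block, the 10 h control arrays of animals 123 and 124 left out, the animal as block with an estimated correlation, and list tests of the 2 comparisons between times. Of 8 list calls 0 were kept under every alternative. Genes named in the report were partly chosen for calls that held, so no share of kept gene calls is given. With the animal as block 1 list was called over both times in place of 3, the named genes TNF at 7 h and CD163 at both times passed, and no other call of a gene named in the report changed. There were then 5384, 6105 and 9425 genes at 7 h, 10 h and over both times. Normexp correction gave 1708 genes at 7 h, 2078 at 10 h and 3927 over both times, and 5 lists at 7 h. Without the filter on dim probes there were 1738 and 2295 genes at 7 h and 10 h, 1 gene for control time, and 8 and 5 lists. With only probes above background on all 16 arrays 1 list was called over both times. With the slide as random block 1 list was called at 10 h. Scan day as block gave 6882 genes at 7 h, 1 gene for control time, and 1 list at 10 h and 1 over both times. With the animal added there were 6610 and 3031 genes at 7 h and 10 h and 1 list at 10 h. With only the 8 arrays compared 1 list was called at 10 h. The cause was not tested for any of these.

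Every probe on its own gave 7107, 8772 and 13645 probes at 7 h, 10 h and over both times, as more items were tested. There were then 5, 7 and 6 lists, from the same lists with each probe of a gene counted as a member. The epithelial list then turned to -2.677, -2.057 and -2.416, and the cause was not tested. Without the 10 h control arrays of animals 123 and 124, 2440 genes were called at 10 h and 1 for control time, with fewer arrays. Camera with an estimated correlation called 0, 0 and 0 lists, likewise 0, 0 and 0 with the animal as block, and fry 7 at 7 h and 9 over both times; the cause was not tested. The authors' table by its headers reversed the direction, with 3201, 2992 and 5777 genes, 4, 3 and 4 lists, and viral probes at -5.96 at 7 h and -6.15 at 10 h, against 9.66 and 9.56 for all Finistère probes in the scanner files, mostly against control signal not above background; its columns hold the opposite group by construction. Leaving out 1 array or animal gave 1400 genes (animal 123) to 4449 (7 h control array of animal 124) at 7 h, 2357 (animal 123) to 4703 at 10 h and 5562 to 8132 over both times. Lists then numbered 2 to 3, 1 to 3 and 1 to 4. For viral probes, where only whole animals were left out, the differences were 9.32 to 10.18 and 9.24 to 9.98. Probes not above background limit fold changes to lower bounds.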
